A study of Mus musculus with 16 samples.

How the data were processed

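Gene expression was measured in mouse lung myeloid cells sorted as positive for CD11c, MHC class II and CD11b, called CD11b+ dendritic cells in the labels. The cells came from lungs bearing Lewis lung carcinoma, a mouse lung tumour line placed in the airways of C57BL/6 mice. The 16 arrays fall into 2 groups by their titles, 8 labelled tumoral and 8 labelled peritumoral. No label says which animal or pool of animals an array came from, so p-values measure the spread between these samples, which may in part be technical.

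Per the labels' protocols, total RNA was extracted with the miRNeasy kit, checked by electrophoresis, amplified with the Ambion WT Expression Kit and labelled with biotin for an Affymetrix whole-transcript array. The authors deposited a value table of 28853 probe sets by 16 arrays, which was read as log2 expression because its values run from 2.31 to 14.33. The log base, the background correction and the normalization are not given in the sources used here, so a log2 difference printed here assumes log base 2. The values are not centred per gene. The array medians were 6.88, 6.93, 6.80, 6.95, 6.85, 6.85, 6.86 and 6.88 for peritumoral 1 to 8 and 6.80, 6.93, 6.81, 6.75, 6.82, 6.90, 6.77 and 6.86 for tumoral 1 to 8. Scanner files were not used here, and neither probe detection calls nor scan batches could be examined. For arrays of this kind the number of arrays limits the precision.

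Probe sets were named through the platform annotation of the value table. A single gene symbol was listed for 21789 probe sets, several symbols for 1621 and none for 5443. Probe sets with several symbols were not used for naming. Where a gene had several probe sets, as 999 genes did, the one with the highest mean over all 16 arrays was kept, which left 19938 genes. The gene identifiers were matched to current symbols through an NCBI table of the GRCm38.p6 assembly, which changed 0 symbols. Genomic coordinates were not used here.

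Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, the label as the only term, 14 residual degrees of freedom), as tumoral minus peritumoral, with Benjamini-Hochberg adjustment over 19938 genes and a threshold of 0.05. There was no filter on dim probe sets. Before the data were examined, 29 gene lists were fixed, 14 for functions and 15 for cell types. The function lists were hypoxia response, glycolysis, oxidative phosphorylation and citrate cycle, MHC class II presentation, co-stimulation and dendritic cell maturation, immune inhibition, inflammatory cytokines and chemokines, interferon response, matrix remodelling and growth factors, cell cycle, lipid and cholesterol handling, microRNA biogenesis, immediate-early and heat-shock stress, and microRNA genes. The marker lists were conventional, type 1 and plasmacytoid dendritic cell, monocyte, macrophage, alveolar macrophage, neutrophil, B cell, T cell, NK cell, lung epithelium, keratin and carcinoma cell, endothelium, fibroblast, and erythrocyte and platelet. Of 463 fixed members 430 were tested. The other 33, Gapdh and Spp1 among them, were not used, 12 because their probe sets name several genes and 21 because no named probe set was found. The microRNA gene list held the 300 tested genes with a microRNA symbol. Lists were tested with camera at its preset correlation of 0.01, two-sided, adjusted over the 29 lists.

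The genes named were also fixed by a rule before the data were examined. It takes the 10 largest rises and 10 largest falls past the threshold, the 3 members of each function list and the 2 of each marker list with the smallest p, the sorting markers Itgax, Itgam and H2-Ab1, and Mir31, Mir210, Mir155, Mir21a and Mir146. No named probe set was found for Mir21a. Genes named outside the rule are said to have been chosen after their values were seen.

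Alternatives fixed in advance were the replicate number as a block or random block, quantile normalization, cyclic loess, centring on the array median, only the genes above the median mean value, trended robust variances, array weights, the mean of all probe sets of a gene, leaving out each array, stricter thresholds, a rank-sum test, camera with an estimated correlation, and fry. After the data were seen, 4 kinds were added: arrays in doubt left out (peritumoral 4 and 7, 1 to 6, or 7 and 8), 1 or 2 principal components of the residuals as covariates, exact permutation of each list's mean per array over all 12870 assignments of the labels, and that test, also of the principal component scores, without arrays in doubt. The value of a list in an array is the mean over its members of the log2 value minus that gene's mean over all arrays.

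limma was tested on simulated data with 200 of 19938 genes changed. On independent noise 79.8%, 95.6% and 99.0% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 85.9%, 96.3% and 99.1% when the arrays' own deviations served as noise. The median numbers of false calls were 9, 10 and 11 on independent noise and 1, 4 and 0 on the arrays' own deviations. The changed genes were drawn at random over all genes, so these shares need not hold for genes of large spread. Principal components were taken over all genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the values per array and the plots.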

Results

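Whole-transcript array values were obtained for CD11b+ dendritic cells, myeloid cells sorted as positive for CD11c, MHC class II and CD11b, from mouse lungs bearing orthotopic Lewis lung carcinoma. The data comprised 8 arrays labelled tumoral and 8 labelled peritumoral. The comparison asked how the transcriptome of these cells differed between tumour and the lung tissue beside it. All differences are given as tumoral minus peritumoral on the log2 scale, and group values as mean ± SD with n = 8.

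Markers of endothelium, fibroblasts and keratin-expressing or carcinoma cells were lower in the arrays labelled tumoral when all arrays were used, whereas no single gene passed the threshold over all genes. Cdh5, the cadherin of endothelial junctions, measured 6.71 ± 0.11 in tumoral and 8.41 ± 1.85 in peritumoral arrays. The difference of -1.70 was carried in large part by peritumoral 4 (12.09) and 7 (10.29) and was -0.78 without both. The labels did not overlap, with the lowest peritumoral value at 6.877 and the highest tumoral value at 6.84. The endothelial list mean differed by -0.88 over all arrays, by -0.45 without peritumoral 4 and by -0.24 without both, and the fibroblast mean by -0.61, -0.36 and -0.28. After adjustment over the lists, 1 list mean passed an exact permutation test without peritumoral 4 and 0 passed without both. Dcn, which encodes the matrix proteoglycan decorin, measured 7.03 ± 0.77 against 9.05 ± 1.35, the largest difference of any gene at -2.02 (limma, adjusted p = 0.239). Of 19 interferon-response genes 18 were higher on average in tumoral arrays, but the mean of the list did not pass between the labels (exact permutation p = 0.184) and the call by camera was lost with an estimated correlation. Hypoxia-response genes did not separate the labels, with 9 members higher and 17 lower.

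limma called 0 of 19938 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.232. At an unadjusted p under 0.05 there were 2292 genes, 1116 higher and 1176 lower in tumoral arrays, where chance gives 997. The rank-sum test also called 0 genes, with 2283 at an unadjusted p under 0.05. The group means of 41 genes were at least 2-fold apart. In 17 genes the groups did not overlap, where chance gives 0.0155% of genes or 3.10. Snord38a, a small nucleolar RNA (+0.74), and Sem1, a proteasome subunit (+0.64), had the smallest unadjusted p-values. Behind genes such as Ier3ip1 (+0.34) and Trav12-2 (-0.30) came Gpr65, a proton-sensing receptor (+0.59), and Sod1, the cytosolic superoxide dismutase (-0.45). All were chosen here after their values were seen, each at an adjusted p of 0.232 in limma. Leaving out peritumoral 7 brought 128 genes past the threshold and leaving out peritumoral 8 brought 20, whereas 0 passed without any other single array.

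The genes of the sorting markers did not pass the test between the labels. Itgax, which encodes CD11c, measured 11.62 ± 0.08 in tumoral and 11.47 ± 0.24 in peritumoral arrays. Itgam, which encodes CD11b, measured 11.31 ± 0.25 and 11.22 ± 0.50, and the MHC class II gene H2-Ab1 measured 13.25 ± 0.08 and 13.21 ± 0.13. Their limma adjusted p-values were 0.508, 0.888 and 0.818.

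**Figure D1:**
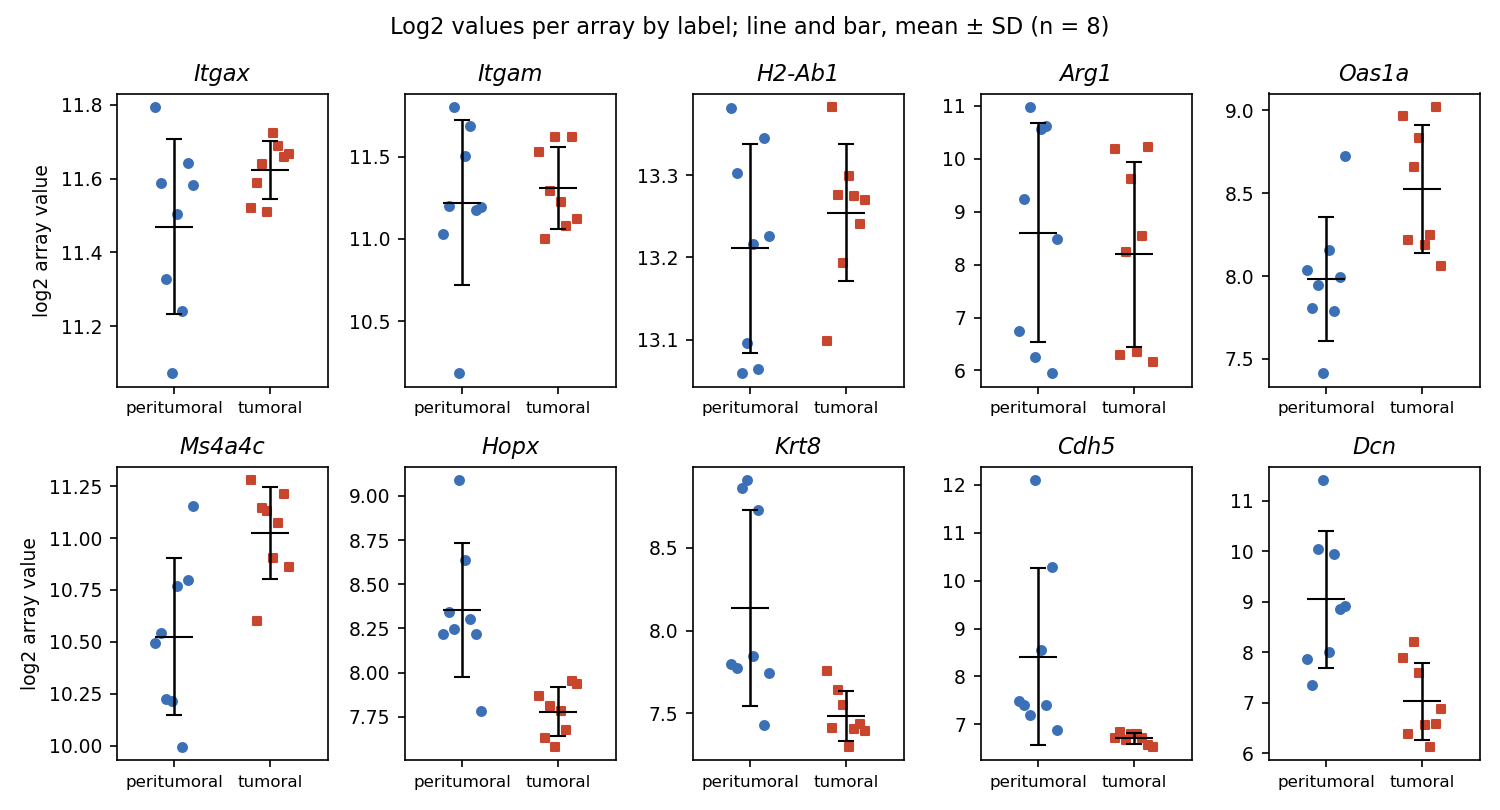
Log2 array values of 10 genes per array, by label, with the mean and SD of 8 arrays as line and bar; each panel has its own axis, and Arg1 was chosen after its values were seen. Cdh5 does not exceed 6.84 in any tumoral array and reaches 12.09 in peritumoral 4, whereas Arg1 spreads from 5.95 to 10.98 over arrays of both labels.

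Among the lists of energy metabolism, oxidative phosphorylation and citrate cycle genes lay slightly higher in tumoral arrays. Of 25 members 17 were higher, with a median difference of 0.08, and camera called the list (adjusted p = 0.00473). The call was lost with an estimated correlation (adjusted p = 0.785), and the list mean did not separate the labels (exact permutation p = 0.390). Without peritumoral 4 the difference of the list mean moved from 0.10 to 0.06, with a camera adjusted p of 0.0260. Adjusted over the list alone 2 members passed, the complex I subunits Ndufa1 (+0.42) and Ndufb5 (+0.39), and 0 passed over all genes. Cox4i1, a subunit of cytochrome oxidase, differed by 0.28. Glycolysis genes were not called (adjusted p = 0.904), with 6 of 16 higher, a median of -0.04 and a camera direction upward, so that median and test differed in sign. Hk1, a hexokinase, differed by 0.14, and Ldha, the lactate dehydrogenase A gene, by -0.36. The muscle-type phosphofructokinase gene Pfkm differed by -0.10. Hypoxia-response genes had a median of -0.04 and were not called by camera (adjusted p = 0.972). Their members with the smallest p went both ways: Ddit4, an inhibitor of mTOR signalling, differed by -0.42, Cited2, a competitor of HIF for its coactivators, by 0.33, and the mitophagy receptor gene Bnip3l by -0.19. For glycolysis and hypoxia, 0 members passed over all genes and 0 adjusted over the list alone.

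Interferon-response genes showed the largest upward shift of any list, with a median difference of 0.35 and 18 of 19 members higher. The 2'-5'-oligoadenylate synthetase genes Oas1a, Oas3 and Oas2, which sense viral RNA, differed by 0.54, 0.47 and 0.37. Camera called the list (adjusted p = 4.46e-06), and the call was lost with an estimated correlation (adjusted p = 0.722). The rise was not shared by all tumoral arrays. The mean of the list per array measured 0.91, -0.64, 0.33, 0.66, -0.36, 0.02, 0.78 and -0.41 in tumoral 1 to 8. In peritumoral arrays it ran from -0.46 to 0.40. The group difference of 0.32 had an exact permutation p of 0.184. No member passed over all genes, and 0 passed adjusted over the list alone.

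Antigen presentation and co-stimulation genes lay slightly higher on average in tumoral arrays, but their list means did not separate the labels (exact permutation p = 0.399 and 0.516). Of 9 MHC class II presentation genes 8 were higher (camera adjusted p = 0.0345; adjusted p = 0.750 with an estimated correlation). Among them were the peptide-loading gene H2-DMa (+0.26), the protease gene Ctss (+0.19) and the transactivator gene Ciita (+0.18). Of 16 co-stimulation and maturation genes 14 were higher (camera adjusted p = 0.0179; adjusted p = 0.785 with an estimated correlation). Il15, a cytokine that sustains NK and memory T cells, differed by 0.36 and was the only member of this list to pass adjusted over the list alone. Tnfsf4, the OX40 ligand gene, and Cd40 differed by 0.34 and 0.30. Immune inhibition genes were split, with 9 of 19 higher, a median of -0.01 and a mean of 0.01 (camera adjusted p = 0.279). In that list the ectonucleotidase gene Entpd1 differed by 0.23 and passed adjusted over the list alone, whereas Ptges, a prostaglandin E synthase, differed by -0.48 and Tgfb1 by 0.14. Of the inflammatory cytokine and chemokine genes 17 of 24 were higher, with Cxcl1 at +0.46, Il6 at +0.41 and Tnf at +0.23. Camera called this list (adjusted p = 0.0127, or 0.722 with an estimated correlation), and 0 members passed adjusted over the list alone. Its list mean differed by 0.13 (exact permutation p = 0.323). Without peritumoral 4 that difference was 0.07, with a camera adjusted p of 0.049997. Over all genes, 0 members of these 4 lists passed.

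Immediate-early and heat-shock genes, which respond within minutes to stimulation or tissue handling, were higher for 13 of 20 members. Fos and Egr2, transcription factor genes of this response, differed by 0.28 and 0.36 and were the 2 members to pass adjusted over the list alone, and Klf6 differed by 0.23. Fos measured 11.69 or less in peritumoral 1 to 6. In peritumoral 7 and 8 it measured 11.88 and 11.95, within its tumoral range of 11.765 to 12.005. Klf6 measured 11.76 and 11.71 in peritumoral 7 and 8, against 11.54 or less in peritumoral 1 to 6. Camera called the list (adjusted p = 0.0243), and the call was lost with an estimated correlation (adjusted p = 0.722). The list mean did not separate the labels over all arrays (exact permutation p = 0.160). Matrix remodelling and growth factor genes were not called (adjusted p = 0.524), with 13 of 25 higher and a median of 0.02 against a mean of -0.06. The collagenase gene Mmp13 differed by 0.60, the urokinase receptor gene Plaur by 0.17 and F13a1, a coagulation factor gene, by -0.36. Cell cycle genes were evenly divided, with 15 of 30 higher and an adjusted p of 0.419 in camera, and their median of -0.003 and mean of 0.006 differed in sign. The replication clamp gene Pcna differed by 0.21, the topoisomerase gene Top2a by 0.28 and Birc5 by 0.23. Lipid and cholesterol handling genes were not called by camera (adjusted p = 0.586), with 10 of 18 higher, a median of 0.04 and a mean of -0.03. The desaturase genes Scd2 and Scd1 differed by -0.61 and -0.86, the latter by -0.46 without peritumoral 4, and the cholesterol transporter gene Npc2 by 0.15. In these 4 lists, 0 members passed over all genes, and beyond Fos and Egr2 0 passed adjusted over the list alone.

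Of 300 microRNA genes 98 were higher and 202 lower in tumoral arrays, with a median of -0.04 and no call by camera (adjusted p = 0.184), whose direction turned with quantile normalization and cyclic loess. Mir17hg, the host gene of the miR-17 cluster, differed by 0.52, Mir18, a member of that cluster, by 0.46 and Mir212 by 0.31. Of the microRNA genes named in advance, Mir31 differed by 0.01, Mir210, a target of hypoxia signalling, by -0.03 (upward after centring on array medians), Mir155 by 0.38 and Mir146 by 0.04. Their limma adjusted p-values lay between 0.586 and 0.967. Such probe sets read long or precursor transcripts and do not give mature microRNA levels. The microRNA biogenesis genes were not called (camera adjusted p = 0.279), with 8 of 12 higher, Ago1 at -0.17, Drosha at +0.15 and Ago4 at +0.14. In both lists, 0 members passed over all genes or adjusted over the list alone.

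Among dendritic and myeloid cell markers, monocyte genes lay higher in tumoral arrays, and macrophage genes did so to an extent that depended on peritumoral 4. Of 12 monocyte genes 9 were higher, and Ms4a4c (+0.50) and Cd14, the lipopolysaccharide co-receptor gene (+0.31), passed adjusted over the list alone. Of 15 macrophage genes 9 were higher, with the lysosomal membrane gene Cd63 at +0.75 and the mannose receptor gene Mrc1 at +0.20, and 0 passed adjusted over the list alone. Camera called both lists at an adjusted p of 0.0243, with an adjusted p of 0.545 for monocytes and 0.755 for macrophages with an estimated correlation. The mean of the monocyte list per array differed by 0.10 and did not separate the labels (exact permutation p = 0.229). The mean of the macrophage list per array differed by 0.09 over all arrays, by 0.02 without peritumoral 4 and by -0.03 without peritumoral 4 and 7 (exact permutation p = 0.589, 0.910 and 0.840). Conventional dendritic cell genes were not called (adjusted p = 0.253), with 9 of 12 higher, Runx3 at +0.19 and Clec10a at +0.23. Type 1 dendritic cell genes were not called either (adjusted p = 0.904), with 6 of 11 higher and a median of 0.05 against a mean of -0.01. In that list Gcsam (-0.37) and Itgae, which encodes CD103 (-0.46), passed adjusted over the list alone. All 6 plasmacytoid genes were lower (camera adjusted p = 0.138), among them Tcf4 (-0.20) and Ccr9 (-0.27). Of 13 alveolar macrophage genes 12 were lower (camera adjusted p = 0.253), with Krt79 at -0.30 and Car4 at -0.89. Without peritumoral 4 the difference of the list mean moved from -0.15 to -0.07 for plasmacytoid and from -0.22 to -0.05 for alveolar macrophage genes, and the camera direction of the latter turned upward. Of 13 neutrophil genes 11 were lower, with the granule genes Lcn2 at -1.25 and Ltf at -0.21 (camera adjusted p = 0.0243; adjusted p = 0.750 with an estimated correlation). Lcn2 was carried by peritumoral 5 (10.86) and 4 (10.29), against 8.21 or less in every other array, and its difference was -0.87 without the former and -0.95 without the latter. The neutrophil list measured 0.97 in peritumoral 5. Its mean differed by -0.36 over all arrays and by -0.22 without peritumoral 4 (exact permutation p = 0.141 and 0.275). Peritumoral 4 had the highest value of the plasmacytoid (0.64), alveolar macrophage (1.24) and neutrophil (1.16) lists. No member of these lists passed over all genes.

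Markers of lymphocytes and of structural lung cells were lower in tumoral arrays, and each of these lists was highest in peritumoral 4. All 14 endothelial genes were lower, with a median of -0.81, among them Cdh5 (-1.70) and Emcn, an endothelial sialomucin gene (-1.45). All 14 fibroblast genes were lower, with a median of -0.41, and Dcn (-2.02), the collagen gene Col3a1 (-0.37) and Sparc (-1.16) passed adjusted over the list alone. Of 11 keratin and carcinoma genes 10 were lower, and Krt8 (-0.65), Tead1 (-0.52) and Yap1 (-0.35) passed adjusted over the list alone. Sparc and Yap1 lie outside the naming rule and were chosen after their values were seen. All 17 lung epithelial genes were lower, with Hopx (-0.57) past the threshold adjusted over the list alone and Ager, a type I pneumocyte gene, at -0.53. Camera gave adjusted p-values of 3.30e-05 for endothelium and for fibroblasts, 0.000843 for keratins and 0.000282 for lung epithelium. All 4 calls were lost with an estimated correlation (adjusted p = 0.722 for each). All 10 T cell genes were lower, with Cd3g at -0.94 and Cd5 at -0.37 (camera adjusted p = 0.00177; adjusted p = 0.722 with an estimated correlation). Of 10 NK cell genes 9 were lower, with Eomes at -0.37 and Klre1 at -0.11 (camera adjusted p = 0.0490; adjusted p = 0.785 with an estimated correlation). All 9 B cell genes were lower without a call by camera (adjusted p = 0.146), with Cd79b at -0.41 and Pax5 at -0.28. Of 4 erythrocyte and platelet genes 3 were lower (camera adjusted p = 0.972), with Pf4 at +0.45 and Ppbp at -0.60. Without peritumoral 4 the difference of the list mean per array moved from -0.32 to -0.06 for NK cells, from -0.28 to 0.003 for B cells, from -0.40 to -0.21 for T cells and from -0.51 to -0.25 for lung epithelium, with unadjusted exact p-values of 0.400, 0.985, 0.192 and 0.190 without that array. Over all genes 0 members of these lists passed, and among endothelial, T, NK, B and erythrocyte or platelet genes 0 passed adjusted over the list alone.

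Of the 29 lists, 3 differed between the labels in an exact permutation test of their mean per array, which was chosen after the data were seen. The differences were -0.31 for keratin and carcinoma genes (exact p = 0.000932, adjusted p = 0.0270), -0.88 for endothelium (exact p = 0.00389, adjusted p = 0.0376) and -0.61 for fibroblasts (exact p = 0.00357, adjusted p = 0.0376). Without peritumoral 4 they were -0.20, -0.45 and -0.36, and only the keratin and carcinoma list passed (exact test, adjusted p = 0.027, 0.0563 and 0.0796). Without peritumoral 4 and 7 they were -0.21, -0.24 and -0.28, and 0 lists passed (adjusted p = 0.0579, 0.0869 and 0.21), with immediate-early genes at 0.13 and an adjusted p of 0.0869. Of the 15 calls by camera, 6 also held after quantile normalization and after cyclic loess, those for interferon response, T cells, lung epithelium, keratins, endothelium and fibroblasts, whereas the other 9 were lost under both. The endothelial list measured 3.46 in peritumoral 4 and 1.26 in peritumoral 7, against 0.18 or less in every other array. The keratin and carcinoma list measured 0.29, 0.91 and 0.23 in peritumoral 3, 4 and 6, against 0.001045 or less in every other array. No test left out just these arrays. Without peritumoral 1 to 6 the difference of the keratin and carcinoma list was -0.14.

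Without peritumoral 4, the differences of 21 of the 79 named genes moved by over 1.5 times. Emcn moved from -1.45 to -0.89, Cd3g from -0.94 to -0.60, Car4 from -0.89 to -0.39, Ager from -0.53 to -0.29, Cd79b from -0.41 to -0.15, Eomes from -0.37 to -0.16, Krt79 from -0.30 to -0.13, Pax5 from -0.28 to -0.08 and Ccr9 from -0.27 to -0.12. The differences of Ctss, Ciita, Top2a, Birc5, Runx3, Clec10a and Itgax became 0.12, 0.09, 0.16, 0.12, 0.12, 0.13 and 0.10, and that of Itgam became -0.06. Other single arrays moved Ppbp from -0.60 to -0.32 (without peritumoral 3), -0.40 (peritumoral 6) or -0.36 (tumoral 2), Pf4 from 0.45 to 0.30 (peritumoral 1), Mir155 from 0.38 to 0.24 (peritumoral 6), Drosha from 0.15 to 0.10 (tumoral 4) and Ciita from 0.18 to 0.11 (peritumoral 5). Itgam ranged from -0.06 to 0.17 without single arrays, and H2-Ab1, Mir31, Mir146 and Mir210, all under 0.05 in size, also moved by over 1.5 times. Camera no longer called 4 lists without this array, MHC class II presentation (adjusted p = 0.0834), macrophages (0.102), neutrophils (0.189) and NK cells (0.309). Without other single arrays camera also called uncalled lists, B cells without peritumoral 3 or 6, cell cycle without peritumoral 3 or tumoral 2, microRNA genes without peritumoral 3, tumoral 2 or tumoral 6, and plasmacytoid cells without peritumoral 3.

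**Figure D2:**
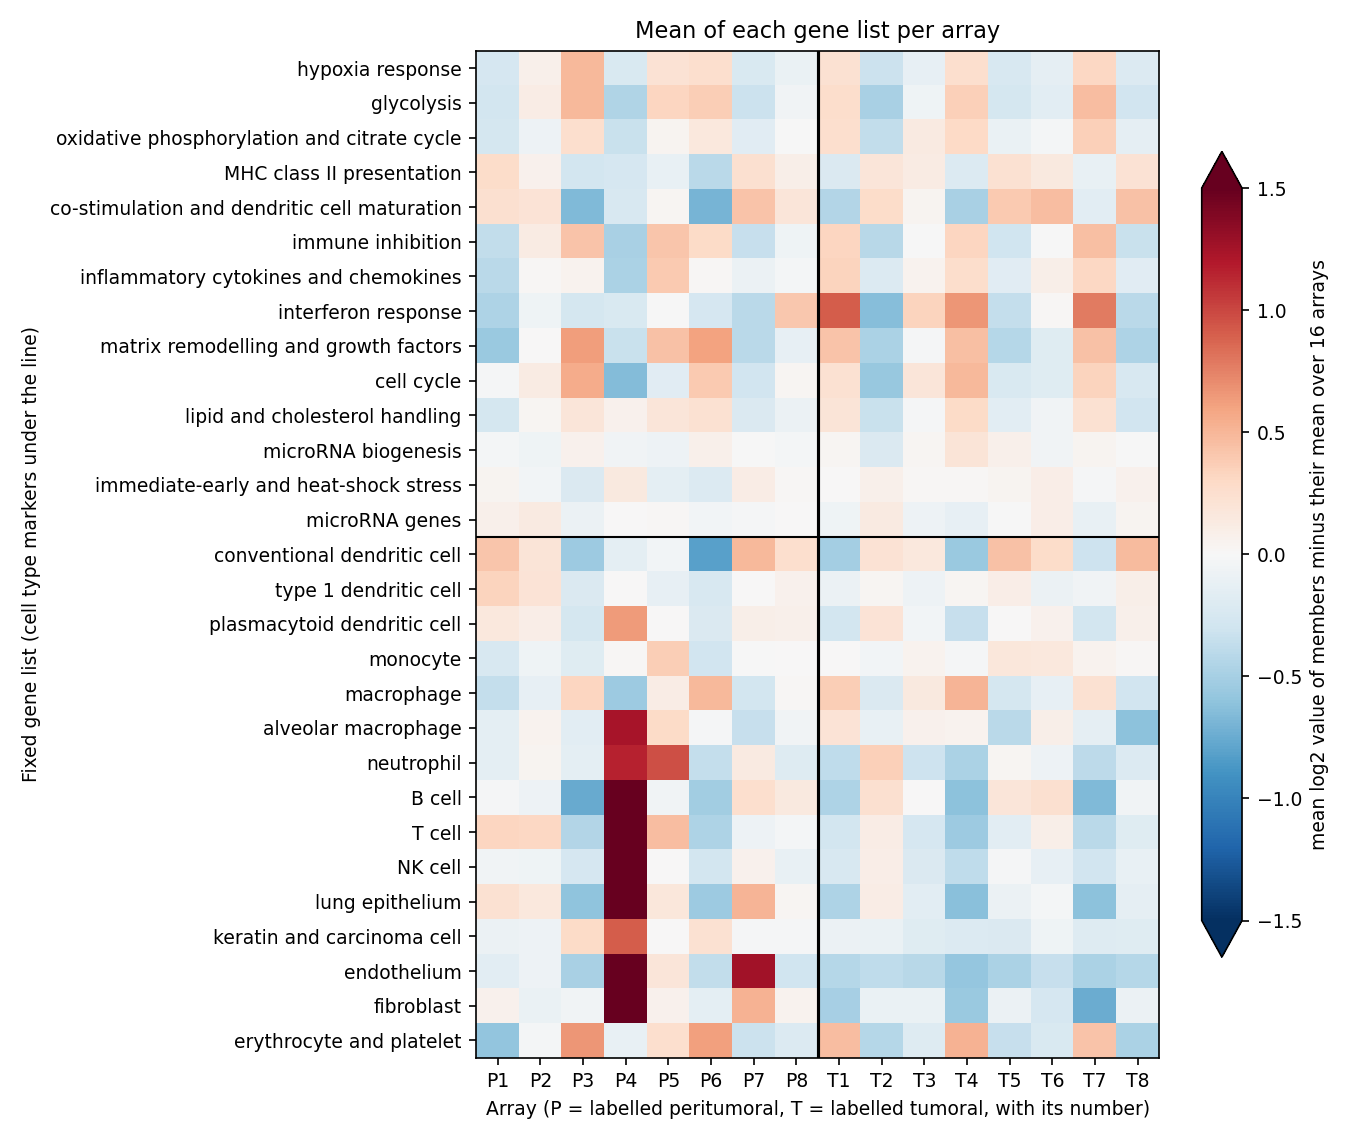
Mean of each of 29 fixed gene lists in each of 16 arrays, as the log2 value of its members minus their mean over all arrays, with functions above and cell types under the horizontal line. Colours stop at 1.5, which 6 lists exceed in peritumoral 4, endothelium (3.46), B cells (2.16), lung epithelium (2.07), fibroblasts (2.01), NK cells (1.96) and T cells (1.53), and the hypoxia and glycolysis lists are high and low in arrays of both labels.

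The largest spread over all genes did not follow the labels. The first principal component held 45.8% of the variance, and the labels differed on it by 11.1 (exact permutation p = 0.394), or by 4.51 without peritumoral 4 (exact p = 0.698). Scores ran from -51.4 to 29.4 in peritumoral and from -27.2 to 38.0 in tumoral arrays. Arg1, the arginase of alternatively activated myeloid cells, had the largest positive span along it and was chosen after its values were seen. The second component held 24.0% of the variance and differed between the labels by -16.9 (exact permutation p = 0.0441), with peritumoral 4 at 52.05 and the next array at 17.8. Without peritumoral 4 the difference on it was -10.7 (exact permutation p = 0.0873).

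**Figure D3:**
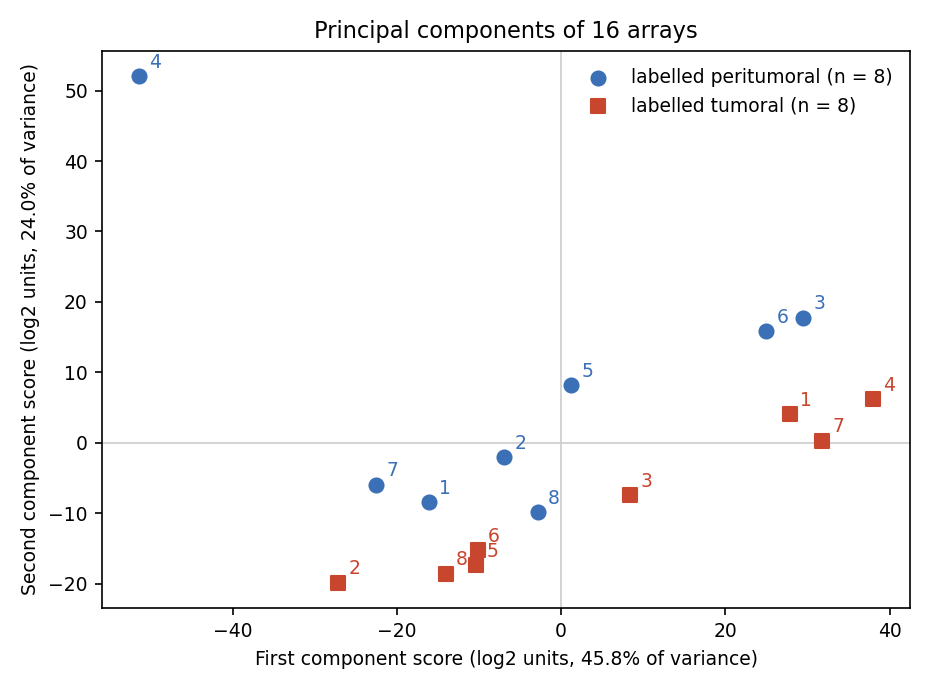
Scores of 16 arrays on the first and second principal components of all genes, in log2 units, with array numbers and labels. Arrays of both labels lie along the whole first component, and peritumoral 4 lies apart at -51.4 and 52.05.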

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

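All tests of an explanation in this part were chosen after the values had been seen. An array was singled out when its gap to the nearest array of the same label exceeded Dixon's 95% value for 8 arrays, taken as a share of the range. Chance does so in about 1 in 20 groups, which for 222 groups tested gives about 11, and 22 were found.

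Peritumoral 4 accounted for 19 of the 22. It was the highest peritumoral array, with its gap as a share of the range in parentheses, for the lists of plasmacytoid dendritic cells (0.529), alveolar macrophages (0.598), B cells (0.654), T cells (0.533), NK cells (0.848), lung epithelium (0.583), keratin and carcinoma cells (0.62), endothelium (0.559) and fibroblasts (0.688). It was also highest for Scd1 (0.8), Tcf4 (0.681), Krt79 (0.664), Cd79b (0.833), Pax5 (0.657), Eomes (0.86), Ager (0.539) and Col3a1 (0.602), and on the second principal component (0.554). The same array was lowest for Ctss (0.541).

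A candidate explanation for peritumoral 4 is RNA of other lung cells among the sorted cells, although a sort on CD11c, MHC class II and CD11b would remove most of them. Scgb1a1 reached 13.06, Sftpc 12.81 and Cdh5 12.09 in it. Markers of endothelium, lung epithelium, fibroblasts, B, T and NK cells were highest in it for 6 of 6 lists. The array stood out through these same lists, so that count decides nothing. Of the sorting marker genes, which were fixed in advance, Itgax (11.07) and Itgam (10.18) were lowest in it of all arrays. H2-Ab1 (13.10) was not, being lower in peritumoral 3 and 6. The low Itgax and Itgam go with RNA of other lung cells but do not exclude other causes, so the explanation stays open. Its deposited values were not compressed, with an interquartile range of 2.666 inside that of the other arrays (2.378 to 3.095). The normalization is not known and may have removed a dim scan from these values, so that range cannot decide on a dim array. A difference of the peritumoral tissue itself was not tested and stays open too.

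Single arrays stood apart in 3 other cases. Peritumoral 5 was highest for the monocyte list (0.539), tumoral 3 was lowest for Mmp13 (0.543) and tumoral 4 was highest for Mrc1 (0.616).

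Counts were repeated on 100 of the 6435 splits of the 16 arrays. For the 0 genes past the threshold this decides nothing, since any split reaches a count of 0 (100 of 100), and the highest other split gave 3688. Chance could not be excluded for either of the other counts. At an unadjusted p under 0.05 the labels gave 2292 genes, 10 of 100 splits gave as many, and the highest other gave 6650. Camera called 15 lists for the labels, 31 of 100 splits gave as many, and the highest other gave 21. The split with 3688 genes was the only 1 of the 100 with any gene past the threshold, and what sets it apart was not tested.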

How the results depend on the processing

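Left-out sets of arrays, residual components and the exact test of list means were chosen after the data were seen. The count of 0 genes held under all alternatives fixed in advance except leaving out single arrays. None of these alternatives had a term for the first principal component or for the recurrence in the deposited order described below. That spread stayed in the residuals, so the count of 0 does not show that the labels do not differ. Without single arrays the ranges were 0 to 128 genes, 0 to 102 higher, 0 to 26 lower, 0 to 7 at least 2-fold, 1752 to 3302 at an unadjusted p under 0.05 and 11 to 16 lists. The counts above 0 came without peritumoral 7 (128 genes) and without peritumoral 8 (20 genes). Of the 15 list calls, 7 were lost without some single array: NK cells for 9 of the 16, MHC class II presentation for 8, co-stimulation and macrophages for 6 each, immediate-early genes and neutrophils for 4 each, and oxidative phosphorylation for 2 (tumoral 4 and 7). Of the uncalled lists, 4 gained a call: microRNA genes for 3 arrays (adjusted p of 0.0124 to 0.0497), B cells for 2 (0.0250 to 0.0417), cell cycle for 2 (0.0241 to 0.0340) and plasmacytoid cells for 1 (0.0425). Testing only genes above the median mean value gave 1476 genes at an unadjusted p under 0.05, with fewer genes tested, and 5 lists. Quantile normalization and cyclic loess gave 6 lists each and turned the camera direction of uncalled lists such as glycolysis, cell cycle and microRNA genes, camera with an estimated correlation 0, fry 0 and the exact permutation of list means 3. The cause was not tested.

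Without peritumoral 4 and 7, which had the highest endothelial values, 88 genes passed (62 higher, 26 lower, 7 at least 2-fold) and 9 lists. Without peritumoral 7 and 8, chosen because leaving out either raised the count, 522 passed (339 higher, 183 lower, 12 at least 2-fold). Arrays chosen in this way make the count no evidence of a difference. With 1 residual component as covariate 324 passed (263 higher, 61 lower, 8 at least 2-fold, 4390 unadjusted), and with 2 components 2676 (1168 higher, 1508 lower, 40 at least 2-fold, 5636 unadjusted). Residual components are by construction unrelated to the label and lower only the spread, so these counts are not calibrated.

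Without peritumoral 1 to 6, which had low small nucleolar RNA values, 2 peritumoral arrays remained, 0 genes passed, 315 were at an unadjusted p under 0.05, and 5 lists reversed in camera. Adjusted p-values were 0.00644 for hypoxia response, now higher (0.00644 to 0.989 over all alternatives), and, now lower, 0.227 for MHC class II presentation (0.00423 to 0.771), 0.00217 for co-stimulation (0.00069 to 0.854), 0.390 for immediate-early genes (0.00081 to 0.722) and 6.81e-05 for conventional dendritic cells (6.8e-05 to 0.974). The cause was not tested.

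The replicate numbers did not pair the arrays. Same-numbered arrays had residual correlations over 0.1 in 3 of 8 pairs, and 0 peritumoral arrays correlated best with their own number. With the number as a replicate block, 0 genes passed, 1985 were at an unadjusted p under 0.05 and 11 lists were called.

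Over all alternatives the named genes kept direction and side of the threshold in 2312 cases, newly passed in 88 and moved in 34. For lists these were 723 the same, 131 no longer past the threshold, 23 newly past it and 74 moved. Signal over background could not be examined.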

Other observations

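The tests in this part were chosen after the values had been seen. Along the first principal component, genes of different functions moved in opposite directions over arrays of both labels. The genes with the largest spans, chosen by that span, were Arg1 (5.52 log2 units from the lowest to the highest array score), the macrophage glycoprotein gene Gpnmb (4.16) and the proteoglycan gene Vcan (4.14). At the other end lay Inmt (-6.32), the club cell gene Scgb1a1 (-6.29) and Retnla (-5.31), a marker of type 2 immunity. Arg1 measured 10.98 in peritumoral 3 and 5.95 in peritumoral 7, and 10.22 in tumoral 7 and 6.16 in tumoral 8. High and low values recurred every 3 arrays in the deposited order, peritumoral 1 to 8 and then tumoral 1 to 8. In peritumoral 1, 4 and 7 and tumoral 2, 5 and 8 Arg1 measured 5.95 to 6.75, against 8.23 or more in every other array. Gpnmb measured 8.17 to 9.105 there, against 10.65 or more elsewhere. Peritumoral 3 and 6 and tumoral 1, 4 and 7 scored 24.96 or more on the first component, against 8.39 or less elsewhere.

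Glycolysis genes had a median span of 1.30 (14 of 16 positive), matrix remodelling genes 1.25 (23 of 25), cell cycle genes 1.15 (30 of 30), interferon-response genes 1.02 (19 of 19), erythrocyte and platelet genes 0.97 (2 of 4), macrophage genes 0.93 (14 of 15), immune inhibition genes 0.83 (16 of 19), oxidative phosphorylation genes 0.74 (25 of 25), hypoxia-response genes 0.65 (21 of 26) and inflammatory cytokine genes 0.62 (16 of 24). These 10 lists lay at or above the 99.79 percentile of 10000 random lists of like expression, as a description of these arrays. The other lists with a positive median were lipid handling (0.45, percentile 94.29), microRNA biogenesis (0.25, percentile 36.07) and monocytes (0.01, percentile 9.74). The remaining 16 lists had negative medians, among them conventional dendritic cells (-1.41, 10 of 12 negative), co-stimulation (-0.85, 15 of 16), B cells (-1.64, 9 of 9), lung epithelium (-1.62, 16 of 17) and endothelium (-2.27, 14 of 14).

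One hypothesis for this spread is that the sample names may not follow the tissue. Arrays with the same label correlated at -0.01 on average and arrays with different labels at -0.09 (exact one-sided permutation p = 0.130). Arrays 3 apart in the deposited order correlated at 0.398 (permutation p = 3e-05, adjusted p = 0.00021 over 7 lags). Neither value tests whether a name matches its tissue. Some values did follow the labels: in 17 genes the groups did not overlap, where chance gives 3.10. The second component also differed between the labels (exact permutation p = 0.0441, or 0.0873 without peritumoral 4). The hypothesis therefore stays open. The recurrence, with its adjusted permutation p of 0.00021, goes against differences between animals unrelated to the deposited order. It was tested after the values had been seen, and the adjustment covers only the 7 lags, so that p-value does not settle the question. Dilution by other lung cells as the whole cause of the Arg1 spread is argued against by the conventional dendritic cell list, which spanned -1.411 where Arg1 was positive. In peritumoral 4, the lowest array on the component, that list measured -0.15, against 0.42 and 0.48 in peritumoral 1 and 7. Dilution therefore stays open for peritumoral 4. The range of Itgax, 0.143 of that of Arg1, decides nothing, since Itgax is among the genes of highest value and Arg1 was picked by its span. RNA of other lung cells stays open for the negative end of the component, where the lists of endothelium, lung epithelium, fibroblasts, B, T and NK cells moved together and peritumoral 4 was the extreme array. An order of sorting or hybridization with the same period and a varying share of macrophages within the sort stay open. All peritumoral arrays precede all tumoral arrays in the deposited order. If arrays were processed in that order, a drift along it could not be told apart from the label difference. No array was reassigned, and the tissue difference as labelled was tested only in the comparison of labels.

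Small nucleolar RNAs, a class chosen because its members had some of the smallest p-values between the labels, had higher means in tumoral arrays for 41 of 51 genes, so that no test of the class between the labels is given. The median of the class per array, relative to its mean over arrays, was 0.15 ± 0.14 (SD, n = 8) in tumoral and -0.15 ± 0.22 in peritumoral arrays. It measured -0.23, -0.26, -0.26, -0.14, -0.19, -0.44, 0.28 and 0.07 in peritumoral 1 to 8 and lay between -0.01 and 0.39 in tumoral arrays. Comparisons of peritumoral 7 and 8 with 1 to 6 were run and dropped, because these arrays had been picked from the same values, and the cause stays open.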
